A study of Homo sapiens with 6 samples.

How the data were processed

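Total RNA from HK2 cells treated for 96 h with OCRL siRNA or non-targeting siRNA was labelled with biotin and hybridised to single-colour Affymetrix GeneChips, 1 array per sample and 3 per group, per the labels' protocols. The labels describe the replicates as independent experiments. The deposited values are log2 probe set intensities normalised across arrays by the authors, with affy and RMA named in the submitters' processing notes and versions not given in the sources used here. The log2 scale was checked on the deposited values, which ran from about 3 to 15 on every array. RMA adjusts the arrays to a common distribution, so a change shared by most genes would be removed before the values were deposited, and it compresses differences of dim probe sets. Precision is limited by the number of arrays.

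The table held 22277 probe sets. The 62 AFFX control probe sets were left out, and 22215 were tested. Genes were named from the platform annotation in GEO, with symbols updated through Entrez identifiers, of which 19052 matched a RefSeq gene table and 0 led to a changed symbol. A single symbol was given for 19064 probe sets, several for 1043, which were not named, and none for 2108, which are unnamed here. A gene was represented by the probe set with the highest mean log2 value over all 6 arrays among those with 1 symbol, which gave 11963 genes. Of these, 4310 had more than 1 probe set, and 45 had probe sets called in both directions.

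Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Values are means ± SD of 3 arrays, and differences are OCRL siRNA minus control siRNA on the log2 scale. SE is the moderated standard error unless another is named. The level of OCRL was also compared by an exact two-sided permutation test over the 20 assignments of the arrays. Before the data were examined, 32 gene lists were fixed, covering pathways around OCRL and general cell processes and 5 sets of markers of other cell types. Of their 1003 genes, 850 were measured under a name. Lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation called 0 of the 32 lists, with 5 at an unadjusted p under 0.05, and fry, which tests whether the genes of a list move one way without comparing them with other genes, called 22. The sign of the median and the direction of the camera test differed in 5 lists, those of phosphoinositide enzymes, proximal tubule, amino acid response, ribosomal proteins and RNA interference, and the mean of the leukocyte list was above 0 with a median below it.

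The genes named were chosen by a rule fixed before the data were examined: OCRL, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 called members of each pathway list with the smallest p, or the 1 member with the smallest p, given as a value, where a list had none called, and several genes fixed by name. A gene fixed by name with no probe set named here was not analysed. Called members of the marker lists with counts of 5 or fewer were named after their values were seen.

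The fit was tested on simulated data built on the 22215 probe sets of this comparison, with 200 changed in each of 10 runs. The S phase genes were also raised by 0.3 on the log2 scale. It recovered 31.2% of 1.25-fold changes, 80.2% of 1.5-fold, 95.2% of 2-fold and 99.8% of 4-fold, and 4.65% of the calls were false. The share of probe sets changed in the simulation was far below the 23.1% called in the data, and its noise was independent between probe sets. These rates therefore describe the simulation and need not hold for this comparison. The alternatives tried were the replicate number as a block, each array left out in turn, quantile normalisation and median centring, eBayes with trend and robust settings, array weights, dim probe sets left out, a 1.5-fold minimum, probe sets ending in _s_at or _x_at left out, and other ways of choosing a probe set per gene. In the setting with dim probe sets left out, dim meant a mean log2 value below the median of all tested probe sets. This setting therefore also dropped probe sets above the lower quartile. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.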

Results

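Gene expression was measured in HK2 cells, an immortalised line of human kidney proximal tubule epithelium, after knockdown of OCRL. OCRL encodes a phosphoinositide phosphatase of endosomes and lysosomes, and its mutation causes Lowe syndrome, a disorder with defective proximal tubule reabsorption. Cells at 30% confluence were transfected with OCRL siRNA or with a non-targeting siRNA, and RNA was taken after 96 h. Each group held 3 arrays from independent experiments, 6 in all, so the number of arrays limits the precision. The deposited table gave 22277 probe sets per array on the log2 scale. The medians of the arrays were 7.24, 7.24 and 7.24 in the control group and 7.28, 7.30 and 7.27 in the OCRL siRNA group. Pearson's r across probe sets, which are not independent replicates, was 0.998 to 0.999 within a group and 0.994 to 0.995 between groups. The first principal component held 66.6% of the variance and the second 12.8%.

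OCRL mRNA fell after transfection of its siRNA. The brighter of its 2 probe sets was at 9.49 ± 0.014 (log2 value, mean ± SD, n = 3) in control cells and at 7.47 ± 0.064 in knockdown cells, which left 24.6% of the control level. This was a 4.06-fold fall (log2 difference -2.02, SE 0.048, adjusted p = 1.24e-05, limma). The dimmer probe set fell 2.01-fold, from 7.64 ± 0.107 to 6.63 ± 0.186 (log2 difference -1.01, SE 0.102, adjusted p = 7.64e-04), which left 49.7%. The knockdown was thus partial by both probe sets. All 3 knockdown arrays lay below all 3 control arrays for both probe sets. The exact two-sided permutation test gave p = 0.10 for each, which is the smallest p that 3 arrays against 3 allow. INPP5B, the closest paralog of OCRL, was at 7.83 ± 0.06 in control cells and 7.82 ± 0.02 in knockdown cells (log2 difference -0.02, adjusted p = 0.863).

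**Figure D1:**
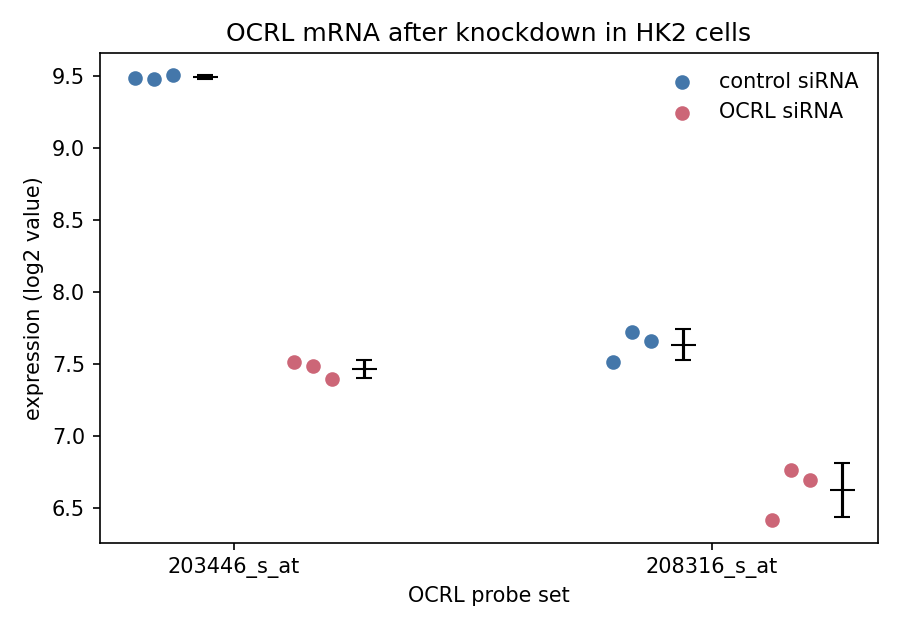
Expression of OCRL (log2 value) in each array for its 2 probe sets, with 3 control siRNA arrays in blue and 3 OCRL siRNA arrays in red; black marks show the mean ± SD. The mean fell from 9.49 to 7.47 for the brighter probe set, on the left, and from 7.64 to 6.63 for the other.

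The question of what else changed in HK2 cells with lowered OCRL mRNA was addressed over all probe sets. The genes with the largest rises were SIGLEC15, a sialic acid-binding lectin known from macrophages and osteoclasts, and the matrix metalloproteinase MMP3. SIGLEC15 rose 7.26-fold, from 6.36 ± 0.23 to 9.22 ± 0.18 (log2 difference 2.86, SE 0.135, adjusted p = 4.97e-05), and MMP3 rose 6.63-fold (log2 difference 2.73, SE 0.194). The collagenases MMP1 and MMP13 rose with it, by 1.93 (SE 0.040) and 1.80 (SE 0.078) on the log2 scale. Other large rises were those of the secretory chaperone SCG5 (log2 difference 2.68, SE 0.040), the lysosomal membrane protein LAPTM5 (2.31, SE 0.182), the thyroid hormone-binding protein CRYM (1.95), the aldo-keto reductase AKR1C3 (1.84) and the transcription factor ETV1 (1.73). The sulfotransferases CHST2 (1.76) and SULT1C2 (1.75) and the chondroitin sulfate enzyme CSGALNACT1 (1.73) completed the 12 largest rises.

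KCTD12 fell most, 5.96-fold from 7.55 ± 0.22 to 4.97 ± 0.19 (log2 difference -2.58, SE 0.135, adjusted p = 7.10e-05), followed by OCRL itself. The vasoconstrictor peptide gene EDN1 (log2 difference -1.67, SE 0.086), the prostaglandin D synthase gene PTGDS (-1.61, SE 0.161), the actin-binding protein gene TAGLN (-1.53, SE 0.063) and the keratin gene KRT7 (-1.49, SE 0.047) also fell. The receptor genes EPHA3 (-1.62), ADGRB3 (-1.48) and GFRA1 (-1.48), the deubiquitinase gene MINDY2 (-1.69), ATRNL1 (-1.86) and the receptor of endoplasmic reticulum autophagy RETREG1 (-1.47) made up the rest of the 12 largest falls. In knockdown cells KCTD12, EPHA3 (4.64) and ATRNL1 (5.23) lay below the lower quartile of every array, so the size of their falls is less certain. AKR1C3 has near-identical paralogs, and its signal was not told apart from theirs. Off-target silencing by the OCRL siRNA was not tested. For KCTD12, which fell more than OCRL, and for the other rises and falls, it was not told apart from an effect of lower OCRL.

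**Figure D2:**
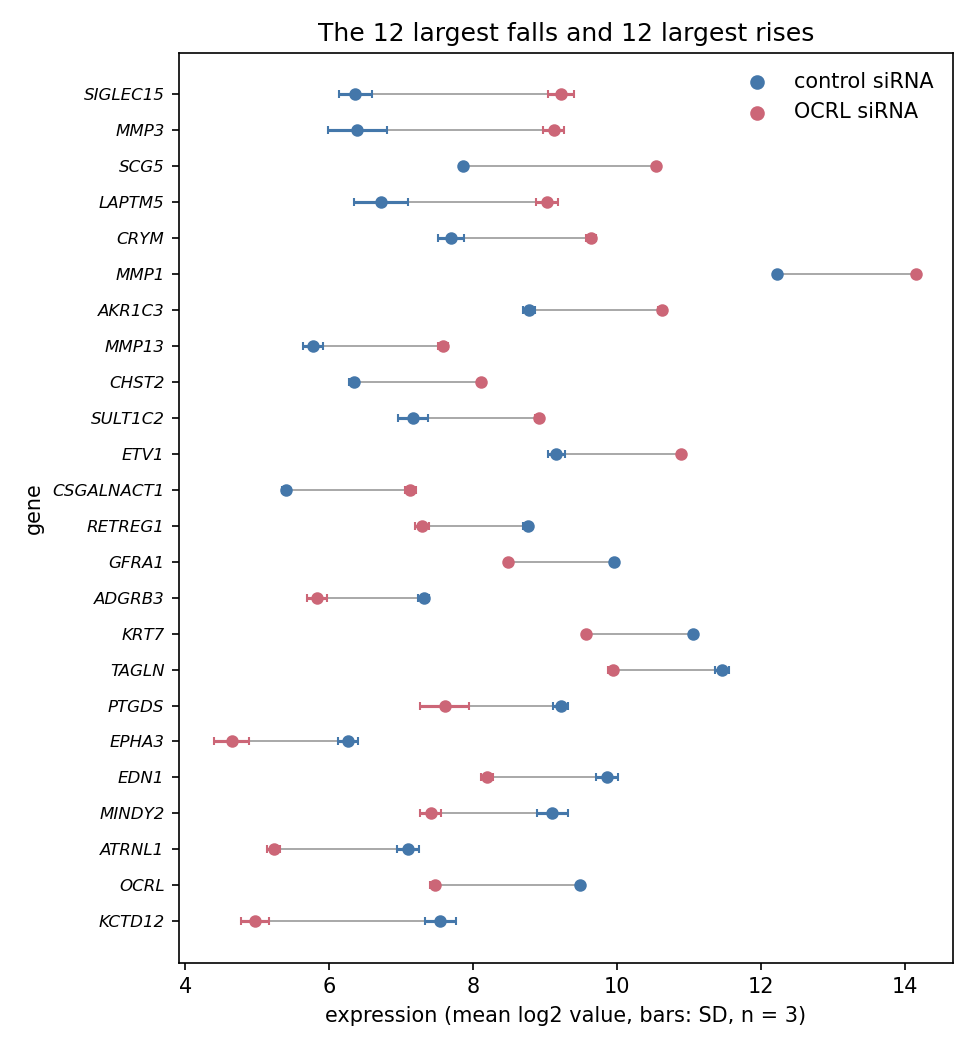
Mean expression (log2 value) of the 12 genes with the largest falls and the 12 with the largest rises, in control siRNA arrays (blue) and OCRL siRNA arrays (red); bars show the SD, n = 3. SIGLEC15 lies at 6.36 in control cells and 9.22 in knockdown cells, and KCTD12 at 7.55 and 4.97.

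Over all 22215 probe sets tested by limma, 5137 changed at an adjusted p under 0.05, 2939 higher and 2198 lower. Taken as 1 probe set per gene, 3105 of 11963 genes changed, 1854 higher and 1251 lower, and in each of them the values of the groups did not overlap. Most changes were small: 806 probe sets passed with at least 1.5-fold and 172 with at least 2-fold. Groups did not overlap in 9036 probe sets, 40.7% of those tested, where chance gives 10%. Among the called genes named here that had other probe sets, none of these was called for EPHA3, ADGRB3, PLCB1, CTSS, NPC1, MAP1LC3B, HIP1, IFT27, FASN, GDF15, IFI44, TJP1, TNC, NDUFA2, DICER1, TFEB and ENG. The share of changed probe sets that were higher depended on the scaling. It was 57.2% as deposited, 52.2% after quantile normalisation and 42.0% after median centring, in which the median of each array was set equal. The medians of the knockdown arrays lay 0.046 above those of the controls. The median log2 difference over all probe sets was -0.007 as deposited and -0.053 after median centring. Centring thus moved the typical probe set down.

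Genes of lysosomal hydrolases rose more often than they fell after the knockdown. Of 36 measured lysosomal enzyme genes, 14 rose, 2 fell and 20 did not pass, and adjusted over the list alone 15 were higher and 2 lower. Among those that rose, CTSS rose 1.88-fold (log2 difference 0.91, SE 0.042), CTSB 1.79-fold (0.84, SE 0.043) and CTSA 1.58-fold (0.66, SE 0.046), and CTSD rose 1.35-fold (0.44, SE 0.056). The list had a median log2 difference of 0.11 (camera adjusted p = 0.00539, adjusted p = 0.244 with an estimated correlation), and after median centring its median was 0.07, with 10 genes higher and 2 lower. Of 41 autophagy genes, 11 rose, among them the cargo receptor SQSTM1 (log2 difference 0.59, SE 0.045) and the ATG8-family genes GABARAPL1 (0.33, SE 0.045), MAP1LC3B (0.33, SE 0.046) and GABARAP (0.30, SE 0.044), while 1 fell and 29 did not pass. Adjusted over the list alone, 12 autophagy genes were higher and 1 lower. Its median was 0.07 (camera adjusted p = 0.0428, adjusted p = 0.244 with an estimated correlation), and after median centring the median was 0.03. The autophagy call was lost in 7 of 16 settings: without control replicate 2 (adjusted p = 0.0702), after quantile normalisation (0.0865) or median centring (0.0712), with dim probe sets left out (0.147), with the mean (0.0674) or the most variable (0.112) of the probe sets of a gene, and with the estimated correlation. Among 10000 random lists matched on mean log2 value, the medians of the lysosomal enzyme and autophagy lists lay at percentiles 98.5 and 92.9. Some random lists thus reached these medians, and a brightness-dependent bias of the arrays was not told apart from them.

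The lists next to these in function did not pass by camera. Of 26 genes of the lysosomal membrane and acidification, 6 rose and 1 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0715). The cholesterol exporter gene NPC1 rose by 0.57 (SE 0.039), the cystine exporter gene CTNS by 0.42 (SE 0.065) and the calcium channel gene MCOLN1 by 0.27 (SE 0.064). MCOLN1 lost its call without control replicate 2 or 3 and without OCRL siRNA replicate 1 or 3 (adjusted p = 0.0767 to 0.0862), after quantile normalisation (0.0502) and after median centring (0.0552). LAMP1 was at 13.35 ± 0.03 in control and 13.49 ± 0.04 in knockdown cells (adjusted p = 0.069), and 2 of its 3 other probe sets were called higher. LAMP1 was also called higher in 4 settings, such as array weights (adjusted p = 0.0304). Of 22 MiT/TFE and nutrient-sensing genes, 8 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0675). The Rag GTPase genes RRAGD (log2 difference 1.61, SE 0.066) and RRAGC (0.77, SE 0.053), the mTORC1 inhibitor gene DDIT4 (1.28, SE 0.070) and, by 1 of its 2 probe sets, TFEB (0.59, SE 0.103), a transcription factor of lysosomal genes, rose, whereas its relative MITF fell (-0.74, SE 0.045). Both lists passed without control replicate 1, with adjusted p of 0.0460 and 0.0449, and by fry, and the MiT/TFE list also passed with trend and robust settings (0.0456).

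Genes of DNA replication and S phase rose. Of 36 measured, 31 rose, 0 fell and 5 did not pass by limma, and 32 were higher and 0 lower adjusted over the list alone. An unadjusted p under 0.05 was found in 32, each of them higher. Thymidine kinase TK1 rose 1.91-fold (log2 difference 0.93, SE 0.058), the replication factor CDC45 1.71-fold (0.78, SE 0.056), the primase PRIM1 1.57-fold (0.65, SE 0.044) and the helicase subunit MCM7 1.51-fold (0.59, SE 0.045). Its median was 0.38 (camera adjusted p = 3.20e-14, adjusted p = 0.109 with an estimated correlation). Of 37 mitosis genes, 15 rose, 1 fell and 21 did not pass, with 16 higher and 1 lower adjusted over the list alone. MKI67 rose by 0.52 (SE 0.044) and the kinase gene AURKB by 0.38 (SE 0.041). The mitosis list had a median of 0.12 (camera adjusted p = 5.09e-04, adjusted p = 0.301 with an estimated correlation), which was 0.08 after median centring. Of 20 p53 targets, 7 rose and 1 fell, or 8 and 2 adjusted over the list alone and 7 and 3 after median centring, among them FAS (1.09, SE 0.060), GDF15 (0.94, SE 0.053), DDB2 (0.80) and BAX (0.50), and the list did not pass (camera adjusted p = 0.139).

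Genes of the type I interferon response rose as well. Of 33 measured, 17 rose, 1 fell and 15 did not pass, and the counts adjusted over the list alone were also 17 and 1. IFI44 rose 2.27-fold (log2 difference 1.19, SE 0.060), IFI44L 2.08-fold (1.05, SE 0.066), the double-stranded RNA sensor TLR3 1.76-fold (0.82, SE 0.052) and HERC5 1.55-fold (0.63, SE 0.041). The list median was 0.24 (camera adjusted p = 2.84e-06, adjusted p = 0.109 with an estimated correlation). Every knockdown array received the OCRL siRNA, so an effect of the reagent was not measured apart from the fall of OCRL. NF-kB and inflammatory genes went both ways, with 4 of 34 higher and 6 lower, or 4 and 8 adjusted over the list alone and 3 and 11 after median centring (camera adjusted p = 0.133). The chemokine gene CCL20 (0.87, SE 0.048) and LTB (0.59, SE 0.042) rose, and the tubular injury markers HAVCR1 (-0.66, SE 0.046) and LCN2 (-0.51, SE 0.050) fell.

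Epithelial genes fell. Of 23 measured, 11 fell, 1 rose and 11 did not pass, with 12 lower and 1 higher adjusted over the list alone. KRT7 fell 2.80-fold, the kidney cadherin CDH6 2.06-fold (log2 difference -1.04, SE 0.041), the adhesion molecule EPCAM 1.75-fold (-0.81, SE 0.049) and the tight junction scaffold TJP1 by 0.32 on the log2 scale (SE 0.039). The median was -0.20 (camera adjusted p = 5.09e-04, adjusted p = 0.116 with an estimated correlation). Mesenchymal and matrix genes did not take the opposite course: 11 of 40 fell and 7 rose, or 12 and 7 adjusted over the list alone (camera adjusted p = 0.0592). TAGLN, TGFB2 (-1.35, SE 0.062) and TNC (-0.70, SE 0.056) fell and TWIST1 rose (0.77, SE 0.048). This list passed without control replicate 2 (adjusted p = 0.0425), control replicate 3 (0.0434) or OCRL siRNA replicate 2 (0.0406), with trend and robust settings (0.0318) and by fry. Of 45 actin regulation genes, 10 fell and 3 rose, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.114), with falls in the Arp2/3 activator gene WASF3 (-0.95, SE 0.044) and the myosin genes MYH9 (-0.50) and MYL9 (-0.44).

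Proximal tubule genes went both ways. Of 30 measured, 6 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.975). The bicarbonate cotransporter gene SLC4A4 fell 2.12-fold (log2 difference -1.08, SE 0.046), and the brush border peptidase genes DPP4 (0.68, SE 0.053) and MME (0.61, SE 0.056) and the amino acid transporter gene SLC7A7 (0.65, SE 0.058) rose. The endocytic receptor megalin, LRP2, lay below the lower quartile of probe sets in both groups, at 3.99 ± 0.04 in control and 3.81 ± 0.09 in knockdown cells (adjusted p = 0.0681). LRP2 was called lower without OCRL siRNA replicate 3 (adjusted p = 0.0372) and after median centring (0.0402). Cubilin, CUBN, was at 5.45 ± 0.09 and 5.33 ± 0.15 (adjusted p = 0.378).

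Genes of the compartments where OCRL acts went both ways. Of 39 endocytosis genes, 5 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.541). The recycling adaptor genes RAB11FIP1 (log2 difference -0.84, SE 0.056) and RAB11FIP2 (-0.45, SE 0.042) and the megalin adaptor gene DAB2 (-0.63, SE 0.044) fell, and HIP1 rose (0.75, SE 0.073). Of 38 phosphoinositide kinase and phosphatase genes, 7 rose and 6 fell, or 8 and 9 adjusted over the list alone and 4 and 9 after median centring (camera adjusted p = 0.662). PIP4K2A rose (0.81, SE 0.055), and PIKFYVE (-0.61, SE 0.052), PLCB1 (-0.66, SE 0.059) and SACM1L (-0.54, SE 0.056) fell. Of 30 genes of retromer and endosome-to-Golgi transport, 5 rose and 4 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.745), with a rise in SNX2 (0.39) and a fall in SNX6 (-0.28). Of 10 OCRL partner and paralog genes, OCRL and CD2AP (-0.52, SE 0.068) fell and MCOLN1 rose, the last with the call lost in 6 of 13 settings, and the counts were the same adjusted over the list alone (camera adjusted p = 0.443). Of 32 primary cilium genes, 10 rose, among them WDR19 (0.42) and IFT27 (0.50), and 3 fell, among them BBS10 (-0.66). The cilium counts were the same adjusted over the list alone (camera adjusted p = 0.152).

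Among metabolic and stress lists, 3 were higher. Of 26 oxidative stress genes, 12 rose and 3 fell, or 12 and 4 adjusted over the list alone, with NQO1 at 2.03-fold (log2 difference 1.02, SE 0.039) and HMOX1 at 1.96-fold (0.97, SE 0.056). As fixed, this list held AKR1C3 and near-identical paralogs of it, so shared signal may be counted more than once. The median was 0.11 (camera adjusted p = 0.0105, adjusted p = 0.301 with an estimated correlation), and 0.06 after median centring. Of 32 hypoxia and glycolysis genes, 13 rose and 0 fell by limma, or 15 and 1 adjusted over the list alone, and 20 had an unadjusted p under 0.05, 18 of them higher. After median centring 9 of these genes were higher and 2 lower, with a median of 0.10. The glucose transporter gene SLC2A3 rose 2.53-fold (1.34, SE 0.105), NDRG1 2.47-fold (1.30, SE 0.053) and VEGFA 1.69-fold (0.76, SE 0.054). The median was 0.15 (camera adjusted p = 0.00528, adjusted p = 0.244 with an estimated correlation). Both lists missed the camera threshold once dim probe sets, those below the median level, were left out, at adjusted p of 0.0841 and 0.0770. Of 41 oxidative phosphorylation genes, 4 rose (NDUFA2, NDUFS7, NDUFB5 and COX7B, by 0.20, 0.21, 0.16 and 0.14), 0 passed adjusted over the list alone by limma, and 16 had an unadjusted p under 0.05. That list had a median of 0.09 (camera adjusted p = 0.0104, adjusted p = 0.535 with an estimated correlation), and after median centring limma called 0 of its genes, with 5 at an unadjusted p under 0.05, its median was 0.04 and its camera adjusted p was 0.0749. The oxidative phosphorylation call was also lost with dim probe sets left out (0.0792) and with the mean (0.0615) or the most variable (0.134) of the probe sets of a gene. With dim probe sets left out, the mean log2 difference of this list stayed at 0.075. NDUFS7, NDUFB5 and COX7B lost their calls in 8 of 13 settings each and NDUFA2 in 6, including leaving out 1 array: control replicate 1, 2 or 3 or OCRL siRNA replicate 1, 2 or 3 for NDUFB5 and COX7B (adjusted p = 0.0548 to 0.124), all but OCRL siRNA replicate 3 for NDUFS7 (0.0507 to 0.103), and control replicate 2 or OCRL siRNA replicate 1, 2 or 3 for NDUFA2 (0.0541 to 0.0670).

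The remaining pathway lists did not pass by camera. Of 12 fatty acid synthesis genes, 5 fell, among them FASN (log2 difference -0.48, SE 0.049) and ACLY (-0.50, SE 0.051), and 2 rose (adjusted p = 0.133). Of 18 cholesterol genes, 3 rose and 3 fell, or 4 and 4 adjusted over the list alone (adjusted p = 0.249), with a fall in HMGCS1 (-0.50) and a rise in EBP (0.34). Of 24 unfolded protein response genes, 9 rose, among them SDF2L1 (0.70) and PDIA4 (0.36), and 2 fell, or 9 and 3 adjusted over the list alone (adjusted p = 0.139). This list passed with the most variable probe set per gene (adjusted p = 0.04997) and by fry. Of 24 amino acid response genes, 4 rose and 6 fell, or 4 and 7 adjusted over the list alone (adjusted p = 0.883), with a fall in VLDLR (-0.59). Of 8 RNA interference genes, AGO1 rose by 0.23 and PRKRA and DICER1 fell by 0.26 and 0.31, with 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.662). AGO1 lost its call in 6 of 13 settings, those without control replicate 2 or 3 or OCRL siRNA replicate 1 or 2 among them (adjusted p = 0.0857 to 0.105). DICER1 lost it without each OCRL siRNA replicate (0.0511 to 0.0587) and with the mean of its probe sets (0.172), and none of its 5 other probe sets was called. Of 39 cytosolic ribosomal protein genes, 0 were called by limma, over all probe sets or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.822). RPL3 was at 13.92 ± 0.02 in control and 13.84 ± 0.05 in knockdown cells, and was called lower with trend and robust settings (adjusted p = 0.0357). The fatty acid counts were the same adjusted over the list alone.

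**Figure D3:**
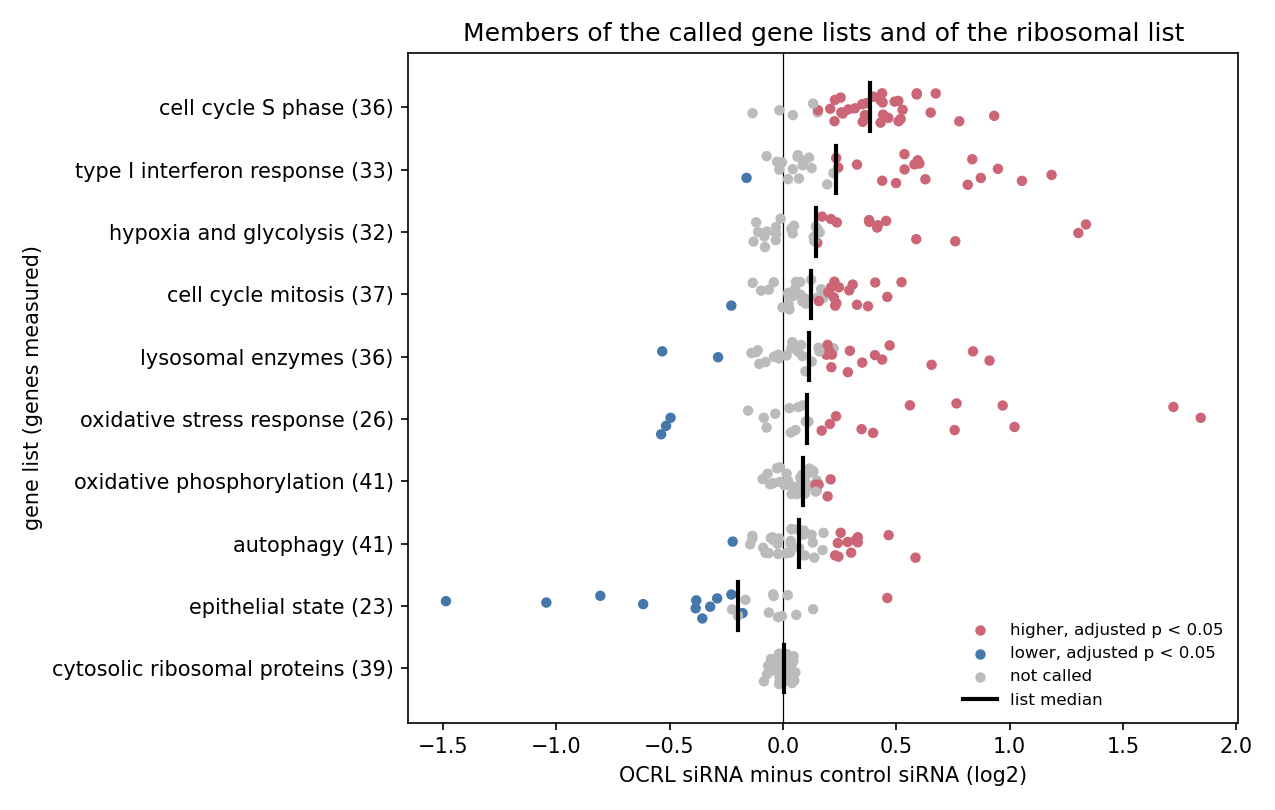
Log2 difference between OCRL siRNA and control siRNA cells for each measured gene of the 9 lists that passed by camera and of the cytosolic ribosomal list, with genes called higher in red, called lower in blue and not called in grey; the black bar is the list median. The median is 0.38 in the S phase list and -0.20 in the epithelial list, and after median centring no oxidative phosphorylation gene is called.

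Markers of other kidney cell types were followed for a change in the makeup of the cultures. Of the 5 marker lists, camera called 0, with 0 at an unadjusted p under 0.05, and fry called 1, the podocyte list. Of 8 podocyte markers PODXL (log2 difference -0.51) and SYNPO (-0.28) fell and TCF21 rose (0.29), with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.133). Of 19 distal tubule and collecting duct markers SCNN1G fell (-0.22) at a dim level, and 0 passed by limma adjusted over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.139). Of 15 endothelial markers ERG (0.91) and ENG (0.27) rose (camera adjusted p = 0.602). Of 14 fibroblast markers FBLN1 (0.60) and TCF21 rose and LUM fell (-0.61) (camera adjusted p = 0.883). Of 19 leukocyte markers LAPTM5 rose (camera adjusted p = 0.662). The counts of these last 3 lists were the same adjusted over the list alone. The 3' minus 5' log2 signal of ACTB, a measure of RNA integrity, was 1.80, 1.57 and 1.48 in control arrays and 1.69, 1.64 and 1.68 in knockdown arrays. Control probe sets for spiked-in transcripts, several per transcript and so not independent, mostly lay higher. Of these, 41 of 45 had a higher mean in knockdown arrays, with a median log2 difference of 0.08. In this set limma called 0, with 9 at an unadjusted p under 0.05. The medians of the autophagy, oxidative phosphorylation, lysosomal enzyme, oxidative stress and mitosis lists, at 0.07 to 0.12, were of similar size. Among random lists matched on mean log2 value, the mitosis, oxidative stress and oxidative phosphorylation medians lay at percentiles 99.8, 99.7 and 99.7. The lysosomal enzyme and autophagy medians lay lower, at 98.5 and 92.9. The spiked-in median was 0.06 after quantile normalisation, where 1 was called, and 0.03 after median centring. The 3 ACTB control probe sets were lower, with a median of -0.17 and none called as deposited (3 at an unadjusted p under 0.05), and -0.22 with 2 called after median centring. The 3 GAPDH control probe sets had a median of -0.01 as deposited, with 0 at an unadjusted p under 0.05 by limma, and -0.06 after median centring.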

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

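All alternatives were fixed before the data were examined. OCRL was called lower in each setting in which its level was computed, at -2.05 to -1.99 with 1 array left out; both its probe sets end in _s_at, so it was absent where these were left out. Without 1 array, limma called 3576 to 4898 probe sets (2108 to 2735 higher, 1468 to 2163 lower) and 2170 to 2986 genes, and camera 9 to 11 lists. A 1.5-fold minimum left 806 probe sets (477 higher, 329 lower) and 502 genes. Without _s_at and _x_at probe sets, fewer were tested, and 2348 (1274 higher, 1074 lower) and 1621 genes were called. With 1 probe set per gene, 3418 were called, 1397 of them lower. Trend and robust settings gave 6378 probe sets, array weights 6185, quantile normalisation 5262 and median centring 5412.

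In place of 9 lists, camera called 5 with dim probe sets left out, 0 with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 22. The S phase, mitosis, interferon, epithelial and lysosomal enzyme lists lost their call only with the estimated correlation among the 16 settings. Autophagy was called in 9 of 16 settings and oxidative phosphorylation in 11, the call by fry counted in each. For autophagy the adjusted p ran from 2.90e-04 by fry to 0.244 by camera with an estimated correlation. For oxidative phosphorylation it ran from 0.00202 to 0.535, both by camera. The cause was not tested. Of 1625 comparisons of 126 named genes, 1565 kept direction and call, 51 lost the call, 7 gained it, and 2 changed sign in genes called in neither setting. COX7B, NDUFB5 and NDUFS7 lost it in 8 settings each, AGO1, MCOLN1 and NDUFA2 in 6 and DICER1 in 4. Levels close to the background limit what can be said of genes such as LRP2. The pseudocount alternative for linear values was not run, because the values are on a log scale.

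With the replicate number as a replicate block, 4571 probe sets (2561 higher, 2010 lower) and 9 lists were called. Same-numbered arrays deviated from their group means with r of 0.14, 0.12 and -0.01, so not every pair deviated together, and the numbers were not taken as pairs. The labels describe the replicates as independent experiments and do not say whether arrays with the same number share an experiment. Pairing by experiment therefore stays open. Of 6 arrays, 4 correlated best with their own number, but these are the pairs of replicates 1 and 2, each counted from both sides. The count expected by chance was not worked out, so this is at most a weak hint towards pairing. If the numbers mark shared experiments, the fit with the block applies, which called fewer probe sets than the 5137 without it. OCRL was lower in both fits, with a limma adjusted p of 0.00122 with the block and 1.24e-05 without.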

Other observations

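The tests of S phase against mitosis genes, of leukocyte markers, of other splits for probe sets and of symbol families were chosen only after the results were seen.

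Zinc finger genes rose more often than they fell. Among 201 groups of at least 8 genes whose symbols open with the same letters, camera called the ZNF group alone. Of 235 measured ZNF genes, most of which encode DNA-binding proteins, 60 rose and 10 fell, with a median log2 difference of 0.09 (adjusted p = 0.0153, adjusted p = 0.965 with an estimated correlation). After median centring 50 rose and 15 fell, with a median of 0.05, and the median as deposited was of similar size to that of the spiked-in control probe sets, 0.08. ZNF443 (log2 difference 0.85, SE 0.078), ZNF93 (0.76, SE 0.042) and ZNF395 (0.72, SE 0.041) rose, and ZNF264 fell (-0.76, SE 0.109). These genes were picked after their values were seen, and related zinc finger genes can share probe signal. The AKR group, with 5 of 8 genes higher and a median of 0.48, came next (camera adjusted p = 0.200), and near-identical genes in it may share signal.

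The rise of S phase genes might reflect a brightness-dependent bias of the arrays, but the median of the list, 0.38, lay at percentile 100 of 10000 lists matched on mean log2 value. If more cells in every phase of the cycle raised S phase and mitosis genes alike, both lists would rise equally. The S phase list rose more, by 0.24 (SE 0.016, not moderated, from the spread between arrays, 95% interval 0.19 to 0.28). An equal response of the lists was assumed and not tested, and both rose, so this difference does not exclude more cycling cells. More cycling cells, a larger share of cells in S phase and a higher level of these transcripts per cell all stay open, since neither cell number nor cycle phase was used here.

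The rise of interferon response genes also lay at percentile 100 of its matched lists, which argues against a brightness-dependent bias of the arrays. Sensing of the OCRL siRNA reagent as foreign RNA could produce it too. Of 5 measured interferon and chemokine genes, limma called 1 higher, IFNA1, from a dim 3.38 to 3.64 (adjusted p = 0.0301), while IFNB1 differed by 0.06 (adjusted p = 0.665) and CXCL10 by 0.27 (adjusted p = 0.0780). This meets neither bound set for the test. Because every knockdown array received the OCRL siRNA, its effect as a reagent and the fall of OCRL cannot be told apart. Off-target silencing was not tested.

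LAPTM5 and SIGLEC15, both known from leukocytes or their relatives, were among the largest rises, and leukocytes in the knockdown cultures could bring them. Of 18 other leukocyte markers, limma called 0 higher; 1 had an unadjusted p under 0.05 and it was not higher. Their median log2 difference was -0.04, the largest was 0.12, and their median level in control cells was 5.60. The SE of that median difference, 0.028, came from the spread across these 18 genes and not from the spread between arrays. PTPRC, TYROBP and LYZ were dimmer than that, at 4.09, 4.44 and 3.75 in knockdown cells, and these 3 were picked after their values were seen. The lack of a rise over the 18 markers argues against such cells as the source, and a change within the HK2 cells was not tested.

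The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5137 probe sets, and 1 split, the real one, gave as many. The highest of the others was 0 by limma, with up to 1294 at an unadjusted p under 0.05. For gene lists the real split gave 9 by camera and the other splits 1 to 5. Every other split mixed arrays of both groups, so the knockdown difference entered the spread within its groups. Low counts there were likely for that reason alone, and lists called there may hold part of that difference. These splits therefore do not measure chance.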
